A study of Mus musculus with 32 samples.

How the data were processed

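Expected counts per gene were read from the deposited RSEM gene tables, each for a single library, with the columns named as per the file headers. Per the submitters' processing notes, reads were aligned with STAR 2.5.2b to the mouse build mm10 and quantified with RSEM 1.3.0, which divides reads shared between genes by a model. The annotation release, the read filters and any trimming are not given in the sources used here. The transcript lengths beside the counts, per the file headers, served to read each library's mean fragment length. The TPM and FPKM columns of the deposited tables were not used here. Per the labels' protocols, libraries were stranded, made from total RNA and depleted of ribosomal RNA.

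The tables held 55487 gene identifiers. Of these, 55394 matched the GENCODE vM21 annotation when version numbers were ignored and 55094 matched with the version. The 93 unmatched identifiers kept their values. Symbols and mm10 coordinates came from that annotation. Of the non-zero values, 11.07% were not whole numbers, and all values were rounded before modelling. The sample groups were read from the labels: 2 genotypes by 4 treatments, with 4 libraries in each of the 8 groups.

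Genes with too few counts were removed with filterByExpr of edgeR on the 8 groups, which left 14869 genes and removed 40618. Library sizes were scaled by TMM. A quasi-likelihood model of edgeR with 1 mean per group was fitted to all 32 libraries with robust dispersions. It had 24 residual degrees of freedom and a common biological coefficient of variation of 7.22%. From this fit 12 contrasts were tested: mutant against wild-type with vehicle, 3 treatments against vehicle in each genotype, the difference of each treatment response between genotypes, and in each genotype the departure of the combined treatment from the sum of the single responses on the log2 scale. P-values were adjusted by Benjamini-Hochberg within each contrast, and genes under 0.05 count as changed. Values are CPM after TMM scaling as mean ± SD of 4 libraries, and log2 fold changes ± SE from the model.

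Gene lists were tested with camera of limma on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the 312 tests of 26 lists in 12 contrasts. The 26 lists were written by hand from general knowledge. A score per library, the mean log2 CPM over a list's tested members, was compared between groups by exact two-sided permutation. With 4 against 4 libraries there are 70 assignments, and the smallest p they can give is 0.0286. Groups, contrasts, tests, lists, the rule for named genes and the other settings to be tried were chosen before the data were examined. Exceptions are the tests and settings named below as chosen after the data or a result were seen.

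The rule names a set of genes in every comparison, among them Gata2, the receptor genes Ifngr1, Ifngr2, Tlr1, Tlr2 and Tlr6, the response genes Irf1, Irf8, Nfkbia and Tnfaip3, and Cd14; a further gene of this set is not reported here. In each contrast it adds up to 8 rises and 8 falls of greatest size among changed genes of at least 5 CPM in some group, without overlap between libraries where 2 groups were compared and leaving out unnamed gene models. From each list it adds up to 3 rises and 3 falls at 1 CPM or more. The text gives a selection of these genes and summarises the others.

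A group in which a gene had no counts was given a floor of 3 counts over the group's libraries, so that such folds are lower bounds; with 1 to 3 counts the ratio is given with a 95% counting interval. Intervals and floors cover counting error only. The structural RNA share is the percentage of counts in 1411 genes for mitochondrial transcripts, microRNAs and small structural RNAs (small nuclear and nucleolar RNAs, 7S RNAs and the RNAs of RNase P and RNase MRP).

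Recovery was tested on simulated counts, drawn from a negative binomial distribution with each gene's mean over all 32 libraries and its estimated dispersion. Counts were drawn independently for each gene, with no variation shared between genes, and genes set to change had to pass a minimum mean count. Recovery and false calls may therefore look better than in the real libraries. Of the genes set to change 1.5-fold, 94% (wild-type IFNg) and 83.6% (mutant Pam3CSK4) were called against vehicle, and 82.1 and 76.1% in the differences of the IFNg and Pam3CSK4 responses. At 4-fold 100% were called in all of these. False calls numbered 3 and 9 among 14510 genes for IFNg and 7 and 6 among 14540 genes for Pam3CSK4. Other splits of the libraries were refitted in the same way on the libraries of each contrast alone.

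Fits used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (1.17.8). Tables and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.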

Results

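RNA was sequenced from mouse fetal liver progenitor cells immortalised with ER-HOXB8, a fusion of the HOXB8 homeobox protein to the hormone-binding part of the estrogen receptor that keeps myeloid progenitors dividing. Per the labels, the line hi-77+/+ carried an intact upstream enhancer of Gata2 and the line hi-77-/- had lost it; they are called wild-type and mutant cells here. Each line was exposed for 4 h to vehicle, to interferon gamma (IFNg) at 1 ng/ml, to Pam3CSK4 at 100 ng/ml, or to both. Pam3CSK4 is a synthetic lipopeptide that activates the receptor pair TLR1 and TLR2. There were 4 libraries in each of the 8 groups. Library totals lay between 44.18 and 71.42 M expected counts, and 17427 to 21034 genes were detected per library. Values are CPM as mean ± SD with n = 4 per group unless stated, changes are log2 fold changes ± SE, and coordinates refer to mm10. The labels do not state whether the 4 libraries of a group came from separate cultures or animals, and each genotype was a single line, so p-values measure only the spread between these samples.

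Gata2 (ENSMUSG00000015053.14, chromosome 6, 88193891 to 88207032) encodes the GATA-family transcription factor whose enhancer was deleted. In wild-type cells it stood at 43.4 ± 8.27 CPM with vehicle, 38.6 ± 1.89 with IFNg, 44.4 ± 2.54 with Pam3CSK4 and 39.1 ± 0.617 with both agents. In mutant cells the values were 7.52 ± 0.679, 6.58 ± 0.408, 7.57 ± 0.257 and 6.98 ± 1.01 CPM. Gata2 was lower in mutant than wild-type vehicle libraries (log2 fold change -2.53 ± 0.10, edgeR adjusted p = 1.0e-19). It did not pass the test in any of the 6 treatment comparisons or the 3 differences between genotypes.

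**Figure D1:**
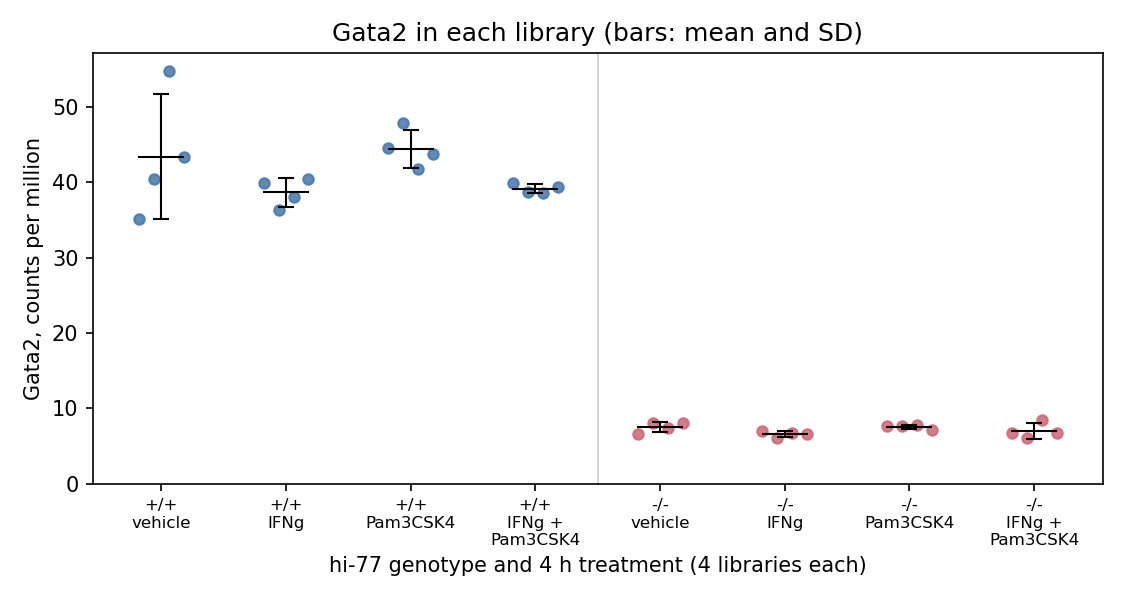
Gata2 in CPM for each of the 32 libraries by genotype and treatment, with points for libraries and bars for mean and SD of 4. The 4 wild-type groups averaged 38.6 to 44.4 CPM and the 4 mutant groups 6.58 to 7.57 CPM.

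The first comparison asked how loss of the enhancer changed progenitors before any stimulus. Mutant cells had less RNA for mast cell, red cell and neutrophil granule proteins and more RNA for early B lymphoid proteins. They also had more RNA from interferon-stimulated genes of the antiviral and MHC class I groups without added interferon. Targets of NF-kB moved in both directions. In edgeR 7980 of 14869 genes differed, 3621 higher and 4359 lower in mutant cells, with 1234 at least 2-fold higher and 864 at least 2-fold lower.

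Of 15 mast cell and basophil genes, 12 were lower and 3 higher in mutant cells (median log2 fold change -3.04, camera adjusted p = 3.3e-05). Ms4a2, a chain of the high-affinity IgE receptor, went from 87.1 ± 7.04 to 1.53 ± 0.23 CPM, and Il1rl1, the receptor for interleukin 33, from 49.0 ± 1.00 to 1.37 ± 0.193 CPM. Of 22 erythroid genes 20 were lower and 1 higher (median -4.55, or -4.14 with undetected members at their bounds, camera adjusted p = 6.8e-14). Pklr, the red cell pyruvate kinase, was at least 589-fold lower, and Car1, a carbonic anhydrase of red cells, at least 222-fold lower. Ank1, the red cell ankyrin, was lower by a ratio of 445 (counting interval 152 to 2160). Of 21 neutrophil granule and maturation genes 19 were lower and 1 higher (median -1.35, camera adjusted p = 1.6e-08): the antimicrobial peptide gene Camp fell by 5.14 ± 0.18 and S100a9 fell by 4.43 ± 0.21, while the collagenase gene Mmp8 rose by 2.00 ± 0.06. Of 14 B lymphoid genes 13 were higher (median 2.65, camera adjusted p = 5.2e-11). Rag1, a subunit of the V(D)J recombinase, went from 2.27 ± 0.281 to 114 ± 1.41 CPM, the surrogate light chain gene Igll1 rose by 4.27 ± 0.09 and the interleukin 7 receptor gene Il7r by 2.90 ± 0.15. The imprinted gene Dlk1 was at least 1590-fold higher and the coactivator gene Ppargc1a at least 672-fold higher.

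Of 32 interferon-stimulated antiviral genes 22 were higher and 3 lower in mutant vehicle libraries (median 0.91, camera adjusted p = 1.9e-07), among them the antiviral GTPase genes Mx1 (log2 5.94 ± 0.15) and Mx2 (4.68 ± 0.11). Of 19 MHC class I presentation genes 15 were higher and 1 lower (median 0.60, camera adjusted p = 7.5e-10). Nlrc5, which activates transcription of MHC class I genes, rose by log2 2.44 ± 0.05 and the heavy chain gene H2-D1 by 1.25 ± 0.03. Of 22 interferon signalling genes 13 were higher and 3 lower (median 0.25, camera adjusted p = 0.0029). The interferon-induced GTPase list (GBP and IRG families) had 11 of 18 members higher (median 2.11, or 1.08 with bounds, camera adjusted p = 3.3e-05), a call lost at an adjusted p = 0.0559 with an estimated correlation. Among the receptors, Tlr1 rose from 0.0316 ± 0.0367 to 1.01 ± 0.213 CPM, Tlr6 from 0.838 ± 0.0661 to 2.94 ± 0.395, and Tlr2 rose to 5.02 ± 0.532 (log2 fold change 1.96 ± 0.12). Ifngr1 and Ifngr2 rose by log2 0.22 ± 0.04 and 0.17 ± 0.05. The transcription factor genes Irf1 and Irf8 rose by 0.99 ± 0.04 and 1.28 ± 0.05. Nfkbia (0.08 ± 0.07) did not pass, Tnfaip3 fell by 1.04 ± 0.11 and the lipopolysaccharide co-receptor gene Cd14 fell by 0.71 ± 0.11.

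Further lists called by camera in this comparison lost the call with an estimated correlation. These were MHC class II presentation (6 of 9 higher, 1 lower, median 0.82, camera adjusted p = 0.0313; adjusted p = 0.0607 with an estimated correlation) and complement and acute-phase genes (1 of 12 higher, 7 lower, median -1.73 or -1.15 with bounds, camera adjusted p = 0.0019; adjusted p = 0.0644 with an estimated correlation). Cholesterol synthesis (18 of 20 lower, 1 higher, median -0.34) had a camera adjusted p = 6.2e-04 and an adjusted p = 0.328 with an estimated correlation. Glycolysis (14 of 17 lower, median -0.23) had a camera adjusted p = 5.8e-04 and an adjusted p = 0.248 with an estimated correlation. Sex-linked transcripts (1 of 5 higher, 4 lower, median -2.15) had a camera adjusted p = 0.0177 and an adjusted p = 0.199 with an estimated correlation. That list holds Xist, the RNA of the inactive X chromosome, and Y-linked genes, which moved in opposite directions, so its test of direction says little. Xist had 0 to 5 counts in wild-type and 17404 to 37062 in mutant libraries. The 4 Y-linked genes stood at 21.6 to 22.8% of their wild-type CPM with vehicle. Ribosome biogenesis (2 of 25 higher, 12 lower, median -0.09) had a camera adjusted p = 0.0446 and an adjusted p = 0.367 with an estimated correlation; its call also ended with RLE size factors (adjusted p = 0.0765) and without mutant vehicle library 2 (0.0513) or 4 (0.051) or wild-type vehicle library 1 (0.0733) or 2 (0.0554).

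The remaining lists had members on both sides and were not called by camera. NF-kB targets and feedback genes had 12 of 34 higher and 13 lower (adjusted p = 0.945), with the transcription factor gene Relb higher by log2 1.32 ± 0.14 and Tnfaip2 lower by -1.64 ± 0.06. Cytokines and chemokines had 9 of 26 higher and 5 lower (0.381), with the chemokine gene Ccl3 higher by 1.35 ± 0.06 and the growth factor gene Csf1 lower by -1.45 ± 0.10. TLR pathway components had 10 of 23 lower and 6 higher (0.513), with Tlr4 at -1.20 ± 0.11. Immediate-early genes had 10 of 25 higher and 11 lower (0.857). Programmed cell death genes had 8 of 21 higher and 7 lower (0.463). Stem and progenitor regulators had 11 of 23 higher and 8 lower (0.645), with the cytokine receptor gene Flt3 at 0.91 ± 0.04 and Ikzf2 at -2.30 ± 0.07. Megakaryocyte genes had 6 of 14 higher and 7 lower (0.604). Monocyte, macrophage and dendritic genes had 12 of 24 higher and 10 lower (0.358), with F13a1 at 2.43 ± 0.05 and the Fc receptor gene Fcgr3 at -2.29 ± 0.04. Cell cycle genes had 17 of 37 lower and 4 higher (0.288). T and NK (4 of 7 higher, 2 lower, 0.135), stromal (5 of 9 higher, 2 lower, 0.139) and hepatocyte genes (2 of 4 higher, 2 lower, 0.671) were mostly too low to test, with 7 of 20, 9 of 20 and 4 of 17 members tested. Adjusted over the list alone, the counts were the same for 23 of the 26 lists. The others were NF-kB targets (13 higher, 13 lower), cell death genes (10 higher, 7 lower) and complement genes (1 higher, 8 lower).

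In 2-group comparisons, 651 of the 721 changes of genes named by list or by default had no overlap between the 4 and 4 libraries. These genes had been called on the same libraries, so this describes them and is no further test. Genes named for the size of their change had been required not to overlap. Camera called 109 of 312 list tests, of which 66 held with an estimated correlation.

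The next comparison asked what IFNg induced in wild-type progenitors. A 4 h exposure raised the transcription factors of the interferon pathway, the GTPases that act against intracellular microbes, antiviral proteins and the machinery of MHC class I presentation. In edgeR 5265 genes changed, 2645 up and 2620 down, with 303 and 169 of them at least 2-fold. With the structural RNA share as a covariate, a setting chosen after the data were seen, 2739 genes changed. That share was 23.9 ± 4.16% with vehicle and 15.9 ± 1.86% with IFNg.

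Irf1 (ENSMUSG00000018899.16, chromosome 11, 53770014 to 53778374), a transcription factor induced by interferon, rose from 11.3 ± 0.712 to 353 ± 3.76 CPM (log2 fold change 4.96 ± 0.05, edgeR adjusted p = 5.4e-40). Irf8, a myeloid transcription factor, rose from 7.34 ± 0.407 to 121 ± 5.39 CPM (4.05 ± 0.05). Of 18 GBP and IRG GTPase genes 15 rose, or 17 adjusted over the list alone (median 6.22, or 6.08 with bounds, camera adjusted p = 1.1e-36). Tgtp2 and Tgtp1, near-identical genes whose reads are hard to separate, rose at least 12900-fold and at least 6100-fold to 181 ± 8.79 and 85.7 ± 7.90 CPM. Iigp1 rose by a ratio of 16200 (counting interval 2910 to 641000), Gbp2 by log2 8.78 ± 0.18 and Igtp by 6.73 ± 0.07. Of 32 antiviral genes 29 rose, or 30 adjusted over the list alone (median 2.13, camera adjusted p = 1.4e-37), with the nucleic acid sensor gene Zbp1 at 7.55 ± 0.31, Oasl2 at 5.83 ± 0.23 and the ubiquitin-like gene Isg15 at 5.51 ± 0.30. Of 19 MHC class I genes 16 rose, or 16 up and 1 down adjusted over the list alone (median 0.45, camera adjusted p = 2.9e-16), with Nlrc5 at 3.26 ± 0.05 and the peptide transporter gene Tap1 at 2.20 ± 0.04. Of 22 interferon signalling genes 14 rose and 4 fell (median 0.80, camera adjusted p = 6.9e-14). Socs1, an inhibitor of JAK signalling, rose by 5.91 ± 0.29 and the receptor gene Ifngr1 fell by 0.21 ± 0.04.

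Of 26 cytokine and chemokine genes 12 rose and 3 fell with IFNg, or 13 and 3 adjusted over the list alone (camera adjusted p = 4.2e-04). Cxcl10 (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889), a chemokine that draws activated lymphocytes, rose from 0.410 ± 0.0897 to 7.38 ± 0.615 CPM (log2 4.16 ± 0.13), while Il15 fell by 0.94 ± 0.07. Of 34 NF-kB list members 11 rose and 5 fell, or 13 and 6 adjusted over the list alone (median 0.13, camera adjusted p = 0.0072; adjusted p = 0.105 with an estimated correlation). The adhesion molecule gene Icam1 rose by 2.25 ± 0.05, and the feedback inhibitors Nfkbia and Tnfaip3 fell (log2 fold changes -0.57 ± 0.07 and -0.62 ± 0.10). Of 21 cell death genes 15 rose and 4 fell (median 0.34, camera adjusted p = 9.9e-07), with the inflammatory caspase gene Casp4 at 2.59 ± 0.18. Ribosome biogenesis genes rose in 17 of 25 cases, or 19 adjusted over the list alone (median 0.22, camera adjusted p = 2.0e-09), with Noc4l at 0.68 ± 0.04. Erythroid genes fell in 12 of 22 cases, or 13 adjusted over the list alone (median -0.33, camera adjusted p = 0.0092). Neutrophil genes fell in 9 of 21 cases (median -0.28, camera adjusted p = 0.0092), a call lost at an adjusted p = 0.271 with an estimated correlation and at 0.237 with the structural share as a covariate. The immediate-early genes Atf3 and Egr2 rose by 4.73 ± 0.27 and 2.95 ± 0.09 and Fos fell by 1.09 ± 0.14. TLR pathway components rose in 10 of 23 cases and fell in 2 (median 0.14, camera adjusted p = 0.0177; adjusted p = 0.0721 with the structural share as a covariate). Tlr6 rose by 1.01 ± 0.12, and Tlr1, Tlr2 and Cd14 did not pass.

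Pam3CSK4 in wild-type cells asked what the TLR1 and TLR2 agonist induced where Gata2 was intact. It raised targets and feedback inhibitors of NF-kB, the acute-phase genes Saa3 and Hp and a few cytokines, and it left the interferon pathway factors near their vehicle levels. Most of the other changes were small. In edgeR 3277 genes changed, 1540 up and 1737 down, with 86 and 103 of them at least 2-fold, and the median size of a change was 0.223 on the log2 scale. The count depended on the libraries. It was 2048 without wild-type vehicle library 4, 2057 when the libraries of this comparison were fitted alone, 648 (408 up and 240 down) without wild-type vehicle libraries 1 and 4, and 155 (141 up and 14 down) with the structural RNA share as a covariate, the latter pair of settings chosen after the data were seen. The structural share was 14.8 ± 1.47% with Pam3CSK4 and 23.9 ± 4.16% with vehicle.

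Of 34 NF-kB targets and feedback genes 27 rose in wild-type cells, or 28 up and 1 down adjusted over the list alone (median 0.93, camera adjusted p = 6.3e-36). Tnfaip3 (ENSMUSG00000019850.11, chromosome 10, 19000910 to 19015657) encodes A20, an enzyme that shuts NF-kB signalling down. It rose from 2.09 ± 0.167 to 16.4 ± 0.469 CPM (log2 fold change 2.98 ± 0.08, edgeR adjusted p = 3.4e-25). Nfkbia, the inhibitor that holds NF-kB in the cytoplasm, rose from 8.48 ± 0.319 to 29.0 ± 0.549 CPM (1.77 ± 0.06). Tnip3, a partner of A20, rose by 5.95 ± 0.15, the NF-kB subunit genes Relb and Nfkb2 by 3.68 ± 0.12 and 2.01 ± 0.06, and the atypical inhibitor gene Nfkbiz by 1.87 ± 0.07. The acute-phase gene Saa3 rose by 7.91 ± 0.29, the oxidase gene Nox1 by 4.44 ± 0.21 and haptoglobin (Hp) by 1.07 ± 0.06. Complement and acute-phase genes rose in 5 of 12 cases, or 5 up and 2 down adjusted over the list alone (median 0.17, camera adjusted p = 0.0012; adjusted p = 0.0558 with an estimated correlation). Cytokine genes, 26 tested, had 7 rises and 2 falls (median 0.31, or 0.17 with bounds, camera adjusted p = 8.5e-04), with Cxcl10 at 3.11 ± 0.14, Tnf at 1.21 ± 0.05 and Ccl3 at 0.95 ± 0.07. TLR pathway components rose in 5 of 23 cases (median 0.12, camera adjusted p = 0.0096), with Tlr2 at 0.84 ± 0.12. The death receptor gene Fas rose by 3.88 ± 0.36 and Casp4 by 1.90 ± 0.19, and Fos and Jun fell (log2 fold changes -1.25 ± 0.14 and -1.18 ± 0.13). Neutrophil genes fell in 12 of 21 cases and rose in 1, or 14 and 1 adjusted over the list alone (median -0.24, camera adjusted p = 0.0028). That call was lost with an estimated correlation (adjusted p = 0.206) and with the structural share as a covariate (0.394). Erythroid genes fell in 7 of 22 cases and rose in 1, or 9 and 1 adjusted over the list alone (median -0.30, camera adjusted p = 0.016), a call that held with an estimated correlation and ended with a prior count of 0.5 (adjusted p = 0.0644). Irf8, Tlr6 and Cd14 did not pass. The GTPase list had a median of 0.28, or -0.12 with bounds, and was not called.

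In mutant cells the question was what the same agonist induced when Gata2 was low. Pam3CSK4 again raised NF-kB targets and their inhibitors, now together with more cytokine genes. In edgeR 3616 genes changed, 1708 up and 1908 down, with 213 and 62 of them at least 2-fold. The structural RNA share was 27.3 ± 2.12% with Pam3CSK4 and 25.7 ± 1.77% with vehicle.

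Of 34 NF-kB genes 32 rose and 1 fell in mutant cells (median 2.27, camera adjusted p = 2.9e-58). Tnfaip3 rose from 1.02 ± 0.147 to 36.9 ± 2.06 CPM (log2 fold change 5.18 ± 0.09, edgeR adjusted p = 5.4e-32) and Nfkbia from 8.92 ± 0.736 to 57.9 ± 4.10 CPM (2.69 ± 0.06). Tnip3 rose by 6.84 ± 0.12 and Relb by 3.71 ± 0.10. Acod1, which makes the antibacterial metabolite itaconate, rose by 4.22 ± 0.14, and Cd40, a receptor of activated antigen-presenting cells, at least 322-fold. Of 26 cytokine genes 15 rose and 2 fell (median 0.86, or 0.61 with bounds, camera adjusted p = 2.2e-11). Cxcl10 rose from 0.181 ± 0.0899 to 16.6 ± 0.728 CPM, the neutrophil-attracting chemokine gene Cxcl2 by a ratio of 451 (counting interval 124 to 3730), and Il1b by log2 4.85 ± 0.25. Saa3 rose by 7.39 ± 0.24, Nox1 128-fold and the costimulatory ligand gene Icosl by 5.16 ± 0.16. Complement and acute-phase genes rose in 5 of 12 cases, or 6 adjusted over the list alone (median 0.46, camera adjusted p = 1.9e-06), with Hp at 2.49 ± 0.07 and C3 at 1.80 ± 0.10. TLR pathway components rose in 10 of 23 cases and fell in 3, or 11 and 3 adjusted over the list alone (median 0.09, camera adjusted p = 0.0119), with the kinase gene Irak2 at 2.24 ± 0.10. Tlr1 and Tlr2 rose by 1.80 ± 0.19 and 1.03 ± 0.10. The monocyte genes Csf1r and Cx3cr1, receptors for macrophage growth factor and fractalkine, rose by 2.85 ± 0.16 and 5.65-fold. The repressor gene Gfi1b rose by 1.41 ± 0.07 and the homeobox gene Meis1 fell by 0.55 ± 0.04. Ifngr1 and Irf1 fell (log2 fold changes -0.48 ± 0.04 and -0.36 ± 0.04), and Ifngr2 rose by 0.46 ± 0.05. The B lymphoid receptor gene Il7r fell by 0.89 ± 0.13. Cholesterol synthesis genes rose in 9 of 20 cases and fell in 1, or 10 and 1 adjusted over the list alone (median 0.14, camera adjusted p = 0.0023; adjusted p = 0.393 with an estimated correlation).

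**Figure D2:**
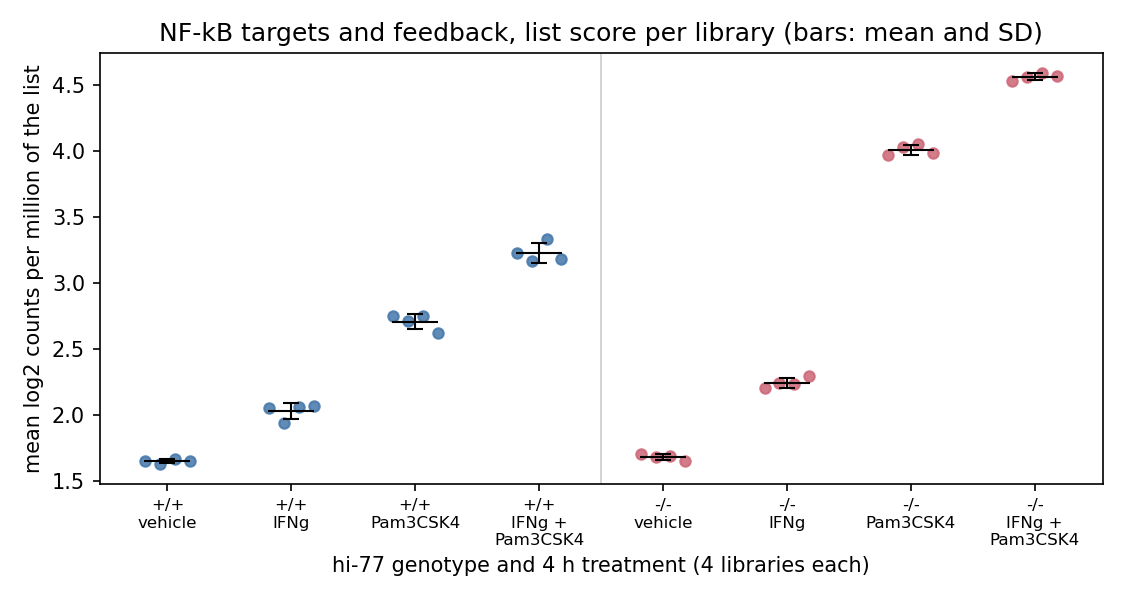
Mean log2 CPM over the 34 tested NF-kB targets and feedback genes for each of the 32 libraries, with points for libraries and bars for mean and SD of 4. The vehicle groups averaged 1.65 and 1.68, and the Pam3CSK4 groups 2.71 in wild-type and 4.01 in mutant cells.

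The difference of the Pam3CSK4 responses addressed whether the mutant line, with low Gata2, reacted to the agonist differently from the wild-type line. NF-kB targets and cytokines rose further in mutant than in wild-type cells. Of the 23 NF-kB targets with a larger rise, 21 also reached a higher level with Pam3CSK4 in the mutant. In edgeR 3956 genes differed in response, 2130 with a more positive and 1826 with a more negative change in mutant cells, 225 and 46 of them by at least 2-fold. This count was 2444 without wild-type vehicle libraries 1 and 4 and 1080 with the structural RNA share as a covariate, both settings chosen after the data were seen. Of the genes that rose, 444 did so in both genotypes, where independent lists would share 176.9. Falls were shared less often than that: 165 genes fell in both, where independent lists would share 222.9.

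Of 34 NF-kB genes 23 had a larger rise in mutant cells, or 26 larger and 1 smaller adjusted over the list alone (median difference 0.91 on the log2 scale, camera adjusted p = 1.7e-27). The mean log2 CPM over the list went from 1.65 ± 0.016 to 2.71 ± 0.059 in wild-type and from 1.68 ± 0.021 to 4.01 ± 0.038 in mutant libraries, each with an exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries can give (0.0427 adjusted). The difference of responses was 2.21 ± 0.12 for Tnfaip3 (edgeR adjusted p = 2.3e-15) and 0.92 ± 0.09 for Nfkbia. For Acod1 it was 3.21 ± 0.22, with 0.660 and 1.36 CPM in wild-type and 0.388 and 7.17 CPM in mutant vehicle and Pam3CSK4 libraries. For Slfn2, a schlafen-family gene, it was 3.33 ± 0.22, largely from a lower start. Its log2 fold change of mutant over wild-type was -2.544 with vehicle and 0.785 with Pam3CSK4. Cytokine genes had a larger response in 10 of 26 and a smaller in 1 (median 0.69, camera adjusted p = 4.7e-07). Ccl3, a chemokine for monocytes, went from 4.40 ± 0.276 to 8.47 ± 0.403 CPM in wild-type and from 11.2 ± 0.611 to 142 ± 7.51 CPM in mutant cells (difference 2.72 ± 0.09, edgeR adjusted p = 2.4e-22). The difference was 3.42 ± 0.28 for Cxcl10 and 3.37 ± 0.43 for Il1b. Among other genes it was 2.06 ± 0.14 for Irak2, 1.39 ± 0.14 for the signalling inhibitor gene Socs3, 2.10 ± 0.18 for Cx3cr1, 1.42 ± 0.09 for Hp, 1.25 ± 0.13 for C3 and 1.25 ± 0.10 for Gfi1b. Complement and acute-phase genes had 3 of 12 larger, or 4 adjusted over the list alone (median 0.21, camera adjusted p = 0.0238; adjusted p = 0.194 with an estimated correlation). Negative differences included Meis1 (-0.64 ± 0.05), the matrix protein gene Thbs1 (-0.76 ± 0.07), the transporter gene Slc22a3 (-0.87 ± 0.08), Irf1 (-0.47 ± 0.06) and Ifngr1 (-0.39 ± 0.06). Cholesterol synthesis genes had 8 of 20 larger and 1 smaller, or 9 and 1 adjusted over the list alone (median 0.15, camera adjusted p = 2.4e-04; adjusted p = 0.285 with an estimated correlation). Tlr1, Tlr2, Tlr6, Irf8 and Cd14 did not differ past the threshold in their response.

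**Figure D3:**
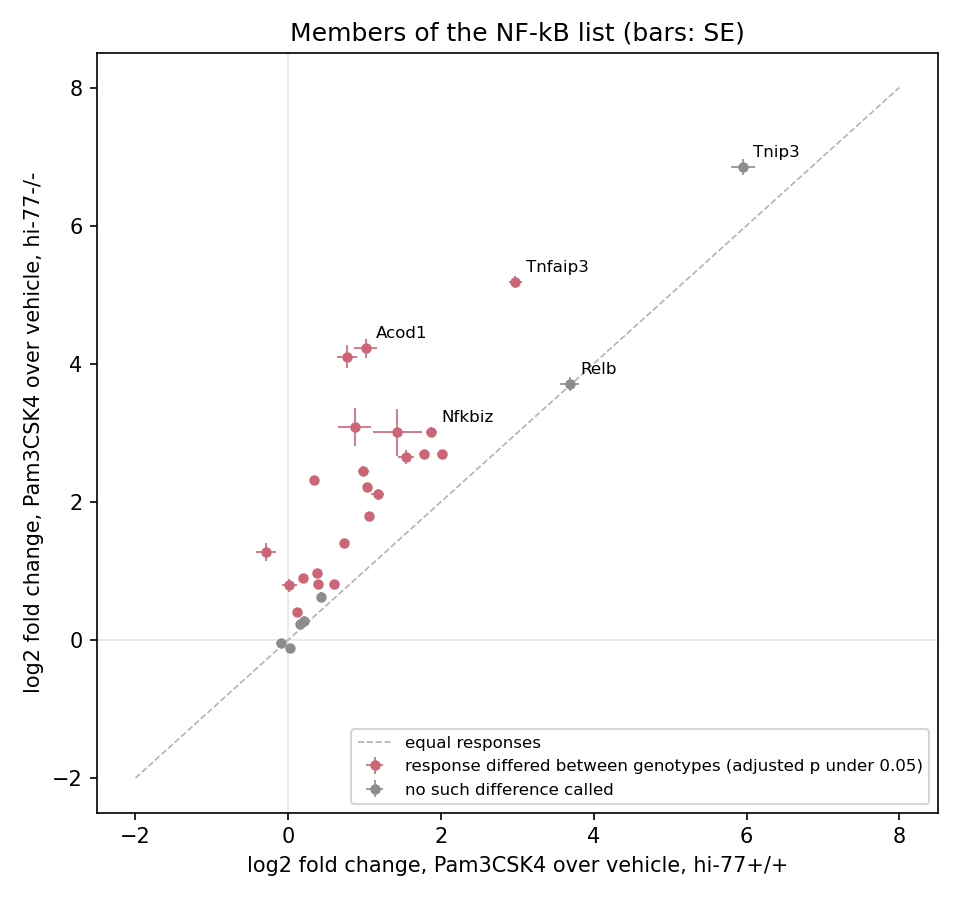
Log2 fold change with Pam3CSK4 in mutant (vertical axis) against wild-type cells (horizontal axis), with a point for each of 29 NF-kB list members above the counting floor in both vehicle groups and error bars for the SE. Tnfaip3 changed by 2.98 in wild-type and 5.18 in mutant cells.

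IFNg in mutant cells asked whether the interferon response was present when Gata2 was low. It was, with GTPase, antiviral, MHC class I and interferon signalling genes again induced, often from higher vehicle levels. Not all called lists were shared. TLR pathway components were called in wild-type cells only (median 0.04 in mutant cells). Immediate-early and cholesterol synthesis genes were called in mutant cells only, and these calls were lost with an estimated correlation. In edgeR 4939 genes changed, 2722 up and 2217 down, with 335 and 125 of them at least 2-fold. The surplus of rises was not kept in every fit: there were 2483 up and 2540 down with RLE size factors, 2360 and 2578 with the CPM filter and 2526 and 2617 in DESeq2. Of the genes that rose with IFNg, 1994 did so in both genotypes, where independent lists would share 484.2.

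All 18 tested GTPase genes rose (median 6.30, or 5.74 with bounds, camera adjusted p = 9.3e-42). Iigp1 rose by a ratio of 47900 (counting interval 13200 to 395000), Gbp5 at least 616-fold and Gbp2 by log2 9.48 ± 0.15. The serine protease inhibitor gene Serpina3f rose at least 1630-fold. Of 32 antiviral genes 30 rose (median 1.95, camera adjusted p = 4.8e-36), with Zbp1 at 8.06 ± 0.27 and Isg15 at 4.80 ± 0.20. Of 19 MHC class I genes 16 rose, or 17 adjusted over the list alone (median 0.60, camera adjusted p = 1.4e-18), with Nlrc5 at 1.76 ± 0.05. Of 22 interferon signalling genes 13 rose and 5 fell, or 14 and 5 adjusted over the list alone (median 0.76, camera adjusted p = 4.9e-11). Irf1 rose from 22.5 ± 1.56 to 493 ± 13.5 CPM (log2 fold change 4.45 ± 0.04, edgeR adjusted p = 3.2e-39), Irf8 by 3.43 ± 0.05 and Socs1 by 6.79 ± 0.26. Ifngr1 and Ifngr2 fell (log2 fold changes -0.47 ± 0.04 and -0.41 ± 0.05). Of 26 cytokine genes 15 rose and 1 fell (median 1.05, or 0.80 with bounds, camera adjusted p = 1.2e-06), with Cxcl10 at 6.23 ± 0.13 and the monocyte chemokine gene Ccl2 at 4.14 ± 0.38. Immediate-early genes rose in 12 of 25 cases and fell in 3, or 13 and 3 adjusted over the list alone (median 0.43, camera adjusted p = 5.7e-04; adjusted p = 0.236 with an estimated correlation), with Atf3 at 6.10 ± 0.24. NF-kB genes rose in 14 of 34 cases and fell in 6, or 14 and 8 adjusted over the list alone (median 0.14, camera adjusted p = 0.0053; adjusted p = 0.093 with an estimated correlation); Nfkbia fell by 0.49 ± 0.07. Cell death genes rose in 15 of 21 cases and fell in 1, or 15 and 2 adjusted over the list alone (median 0.31, camera adjusted p = 2.2e-07). Ribosome biogenesis genes rose in 20 of 25 cases and fell in 1, or 22 and 1 adjusted over the list alone (median 0.26, camera adjusted p = 6.2e-11). B lymphoid genes fell in 6 of 14 cases, or 7 adjusted over the list alone (median -0.40, camera adjusted p = 0.005), with Igll1 at -0.63 ± 0.07 and Rag2 at -0.70 ± 0.05. The chemokine receptor genes Cxcr4 and Cxcr2 fell (log2 fold changes -1.09 ± 0.04 and -1.70 ± 0.14), and the cyclin gene Ccng2 fell by 1.45 ± 0.06. Tlr1 and Cd14 did not pass.

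The difference of the IFNg responses was small beside the responses themselves. Irf1, Irf8 and Nlrc5 rose by less in mutant cells from a higher start, and several cytokine genes rose by more, among them Cxcl10 and Csf1 from a lower start. In edgeR 245 genes differed, 123 with a more positive and 122 with a more negative response in mutant cells, 17 and 7 of them by at least 2-fold. This count was 127 when the libraries of this comparison were fitted alone and 400 in DESeq2. It was 136 without mutant IFNg library 1, 159 and 157 without wild-type IFNg library 2 or 3, and 382 and 138 without wild-type vehicle library 2 or 4.

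Among named genes the difference was largest for Tubb3 (ENSMUSG00000062380.4), a tubulin isotype known from neurons, which went from 4.94 ± 0.553 to 143 ± 5.26 CPM in wild-type and from 0.194 ± 0.0645 to 66.6 ± 5.28 CPM in mutant cells (difference 3.57 ± 0.18, edgeR adjusted p = 1.6e-15). It was 2.07 ± 0.27 for Cxcl10, 1.99 ± 0.22 for Slfn2, 0.99 ± 0.13 for the macrophage growth factor gene Csf1 and 0.99 ± 0.12 for Il12rb1, a receptor chain for interleukin 12. Cxcl10, Csf1 and Slfn2 (log2 fold change -2.54) stood lower in mutant than wild-type vehicle libraries, and levels with IFNg were not tested between genotypes. Cytokine genes had 4 of 26 with a larger response, or 6 adjusted over the list alone (median 0.23, camera adjusted p = 2.5e-06). Nlrc5 went from 13.7 ± 0.731 to 131 ± 10.1 CPM in wild-type and from 74.3 ± 2.11 to 252 ± 17.9 CPM in mutant cells (-1.50 ± 0.07, edgeR adjusted p = 3.1e-17). The pore-forming protein gene Mpeg1 had a difference of -1.30 ± 0.07, Irf1 of -0.51 ± 0.06, Irf8 of -0.62 ± 0.07, Tap1 of -0.51 ± 0.06 and Irf9 of -0.55 ± 0.08, while Stat2 had 0.52 ± 0.08. Interferon signalling genes had 7 of 22 smaller and 2 larger responses, or 9 and 2 adjusted over the list alone (median -0.06, camera adjusted p = 0.0301; adjusted p = 0.0837 with an estimated correlation). That call also ended with the structural share as a covariate (0.0728) and without mutant vehicle library 3 (0.0672) or wild-type vehicle library 1 (0.0579). GTPase genes had 5 of 18 smaller, or 6 adjusted over the list alone, among them Gbp7 (-0.74 ± 0.10) and Ifi47 (-0.83 ± 0.13). Their median was -0.18 while camera gave the opposite sign (adjusted p = 0.0011), a call lost at an adjusted p = 0.137 with an estimated correlation and at 0.669 with a prior count of 0.5. Tlr1, Tlr2, Nfkbia, Tnfaip3 and Cd14 did not differ in response past the threshold. For Tlr6 the difference was -0.72 ± 0.16.

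The combined treatment asked how the agents acted together, first in wild-type cells. Interferon targets and NF-kB targets rose together, and Cxcl10 stood at 216 CPM, against 7.38 CPM with IFNg and 3.56 CPM with Pam3CSK4 alone. In edgeR 6491 genes changed, 3154 up and 3337 down, with 375 and 316 of them at least 2-fold; with the structural RNA share as a covariate the count was 3361 (1880 up and 1481 down), and with the CPM filter rises also outnumbered falls (3250 and 3015). The structural share was 13.6 ± 0.611% with both agents.

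All 18 GTPase genes rose in wild-type cells (median 6.91, camera adjusted p = 1.6e-34), with Gbp5 at least 1390-fold and Tgtp2 at least 20700-fold higher. Of 32 antiviral genes 29 rose, or 30 up and 1 down adjusted over the list alone (median 2.25, camera adjusted p = 2.2e-32). The NF-kB list had 30 of 34 higher (median 1.53, camera adjusted p = 1.9e-23), with Tnfaip3 at 2.75 ± 0.08, Nfkbia at 1.53 ± 0.06, Tnip3 at 5.74 ± 0.16 and Cd40 by a ratio of 562 (counting interval 101 to 22200). Of 26 cytokine genes 19 rose and 3 fell, or 19 and 4 adjusted over the list alone (median 1.38, or 1.20 with bounds, camera adjusted p = 1.4e-07). Cxcl10 reached 216 ± 4.66 CPM (log2 fold change 9.03 ± 0.11, edgeR adjusted p = 8.2e-34) and Cxcl9, a related chemokine gene, rose at least 218-fold. Irf1 and Irf8 rose by 5.19 ± 0.05 and 4.20 ± 0.05. MHC class I genes rose in 18 of 19 cases (median 0.63, camera adjusted p = 1.1e-19) and ribosome biogenesis genes in 23 of 25 (median 0.33, camera adjusted p = 5.0e-12). Cell death genes rose in 15 of 21 cases and fell in 3 (median 0.33, camera adjusted p = 1.5e-07), with Fas at 4.53 ± 0.34 and Casp4 at 3.88 ± 0.17. Erythroid genes fell in 14 of 22 cases and rose in 1 (median -0.51, camera adjusted p = 0.0127). Complement genes (median 0.25, camera adjusted p = 0.0128) and neutrophil genes (median -0.34, camera adjusted p = 0.0317) lost the call with an estimated correlation (0.145 and 0.379). Interferon signalling genes rose in 14 of 22 cases and fell in 3 (median 0.82, camera adjusted p = 7.2e-12), and TLR pathway components rose in 12 of 23 and fell in 2 (median 0.20, camera adjusted p = 0.0032). Ifngr1 fell by 0.33 ± 0.04, Tlr2 and Tlr6 rose by 1.23 ± 0.12 and 1.12 ± 0.12, Fos fell by 2.27 ± 0.15 and Cd14 did not pass.

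In mutant cells the combined treatment again raised interferon targets, NF-kB targets and cytokines. Immediate-early and cholesterol synthesis genes were called in mutant cells only (camera adjusted p = 0.0019 and 0.0041), calls lost with an estimated correlation (0.285 and 0.417). Erythroid and neutrophil genes were called in wild-type cells only. In edgeR 6513 genes changed, 3519 up and 2994 down, with 522 and 296 of them at least 2-fold. This surplus of rises ended with RLE size factors (3287 up and 3282 down), in DESeq2 (3310 and 3308) and without combination library 1 (3048 and 3048), and turned with the CPM filter (3007 and 3260). Gbp5 rose at least 8800-fold, Serpina3f at least 8350-fold, Cd40 at least 2830-fold and Cxcl9 at least 1300-fold. Cxcl10 reached 847 ± 55.1 CPM (log2 fold change 12.20 ± 0.12, edgeR adjusted p = 3.0e-36). All 18 GTPase genes rose (median 6.78, or 6.32 with bounds, camera adjusted p = 2.8e-30), and 31 of 32 antiviral genes rose and 1 fell (median 2.17, camera adjusted p = 1.1e-25). Of 34 NF-kB genes 31 rose, or 33 adjusted over the list alone (median 2.63, camera adjusted p = 7.9e-33), with Acod1 at 7.17 ± 0.13, Tnip3 at 6.81 ± 0.12, Tnfaip3 at 5.24 ± 0.09 and Nfkbia at 2.51 ± 0.06. Of 26 cytokine genes 20 rose, or 21 adjusted over the list alone (median 3.03, camera adjusted p = 2.2e-16). Complement genes rose in 9 of 12 cases, or 9 up and 1 down adjusted over the list alone (median 1.22, camera adjusted p = 2.1e-04), with the factor B gene Cfb at least 214-fold higher. Irf1 and Irf8 rose by 4.67 ± 0.05 and 3.58 ± 0.05. Fas and Casp4 rose by 6.47 ± 0.29 and 4.61 ± 0.14. Ifngr2, Tlr1, Tlr2 and Tlr6 rose by 0.47 ± 0.05, 1.48 ± 0.19, 1.53 ± 0.10 and 0.59 ± 0.10, Ifngr1 fell by 0.88 ± 0.04 and Cd14 did not pass. The falls included Cxcr4 (-1.89 ± 0.04), Ccng2 (-2.02 ± 0.06), Meis1 (-1.10 ± 0.04) and the myeloid receptor gene Cxcr2 (-2.09 ± 0.15). MHC class I genes rose in all 19 cases (median 0.76, camera adjusted p = 2.0e-18) and ribosome biogenesis genes in 24 of 25 (median 0.32, camera adjusted p = 2.3e-11). Interferon signalling genes rose in 18 of 22 cases and fell in 2, or 19 and 3 adjusted over the list alone (median 0.86, camera adjusted p = 2.5e-13). TLR pathway components rose in 14 of 23 and fell in 2, or 14 and 3 adjusted over the list alone (median 0.19, camera adjusted p = 0.0029), and cell death genes rose in 13 of 21 and fell in 2 (median 0.28, camera adjusted p = 6.4e-06).

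Between genotypes, the response to both agents differed for 2347 genes in edgeR, 1308 with a more positive and 1039 with a more negative change in mutant cells, 154 and 58 of them by at least 2-fold. The count was 1274 without mutant combination libraries 3 and 4 and 1216 with the structural RNA share as a covariate, both chosen after the data were seen. The balance of directions turned in other fits: 710 more positive and 1184 more negative with the libraries of this comparison alone, 1056 and 1630 with the CPM filter, and 980 and 1598 without mutant combination library 1. NF-kB targets and cytokines again responded more in mutant cells, while genes such as Nlrc5 and Irf1 responded less. Of 34 NF-kB genes 25 had a larger response, or 27 adjusted over the list alone (median 0.92, camera adjusted p = 5.1e-36). Of 26 cytokine genes 11 had a larger response, or 13 adjusted over the list alone (median 1.05, camera adjusted p = 6.2e-21). The difference was 2.48 ± 0.12 for Tnfaip3 (edgeR adjusted p = 4.0e-17), 0.98 ± 0.09 for Nfkbia, 3.17 ± 0.27 for Cxcl10, 3.54 ± 0.21 for Acod1, 2.44 ± 0.08 for Ccl3, 3.22 ± 0.43 for Il1b and 4.06 ± 0.17 for Tubb3. The metalloreductase gene Steap4 stood at 5.80 ± 0.206 CPM in treated mutant libraries and at 0.0421 to 0.0664 CPM in the other groups of this comparison. Socs3, Hp and C3 had differences of 0.84 ± 0.13, 1.55 ± 0.09 and 1.47 ± 0.13. Complement genes had 4 of 12 larger, or 5 adjusted over the list alone (median 0.24, camera adjusted p = 0.0052; adjusted p = 0.101 with an estimated correlation). Cholesterol synthesis genes had 14 of 20 larger, or 15 adjusted over the list alone (median 0.31, camera adjusted p = 2.8e-10; adjusted p = 0.0607 with an estimated correlation), with Msmo1, a sterol oxidase gene, at 0.87 ± 0.14. Erythroid genes had 5 of 22 larger and 1 smaller, or 8 and 2 adjusted over the list alone (median 0.23, camera adjusted p = 0.0242), a call that ended with a prior count of 0.5 (0.0763) and with the structural share as a covariate (0.0647). Smaller responses were seen for Nlrc5 (-1.67 ± 0.07), Mpeg1 (-1.67 ± 0.07), the deubiquitinase gene Usp18 (-1.42 ± 0.17), Ifi47 (-1.13 ± 0.12), Irf7 (-1.13 ± 0.17), Irf8 (-0.62 ± 0.07), Irf1 (-0.52 ± 0.06) and Ifngr1 (-0.55 ± 0.06). Ifngr2 had 0.57 ± 0.07. Tlr1, Tlr2 and Cd14 did not differ past the threshold.

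**Figure D4:**
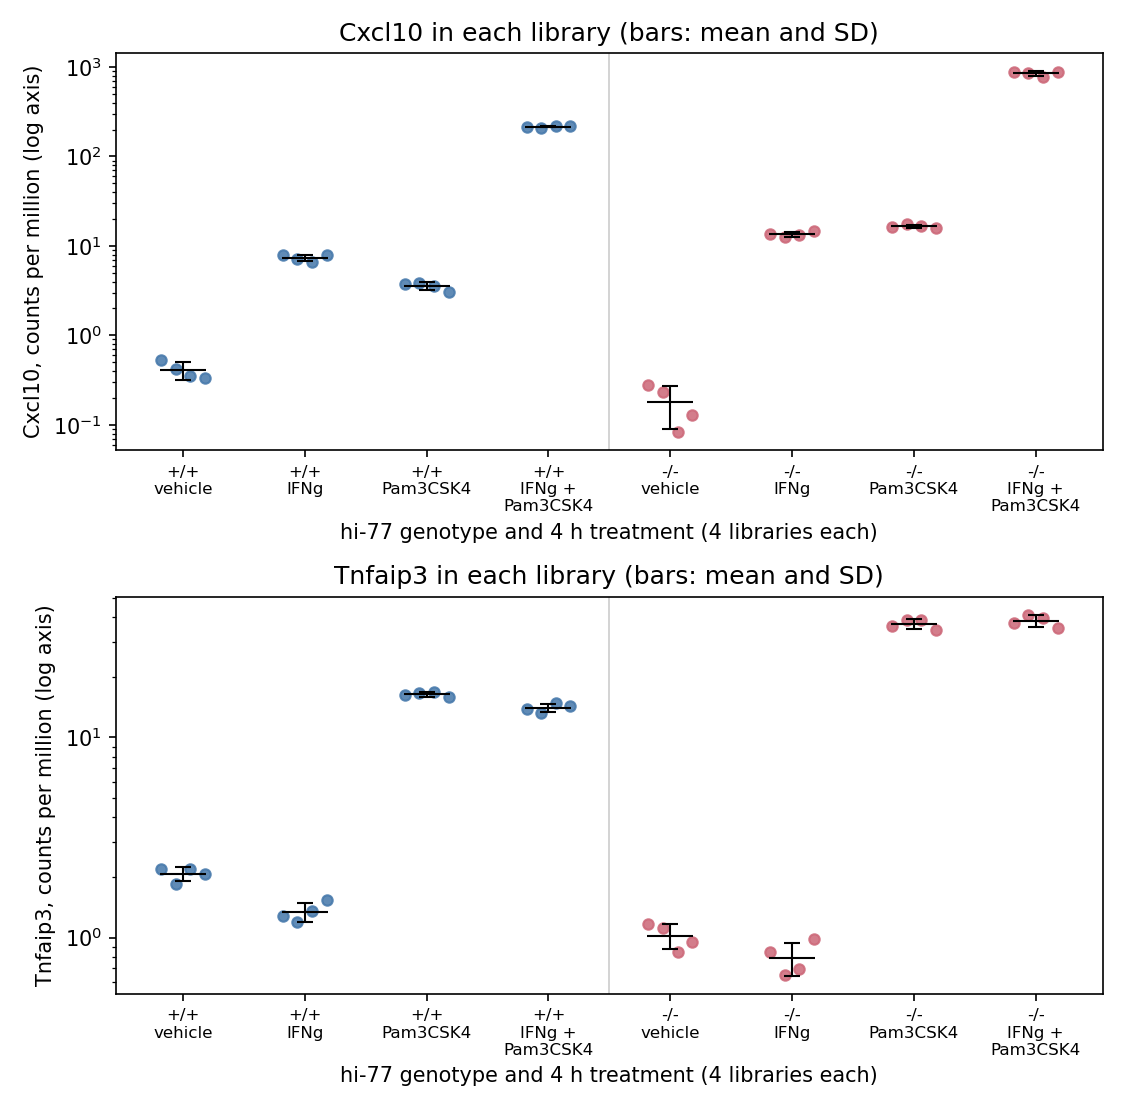
Cxcl10 and Tnfaip3 in CPM on log axes for each of the 32 libraries by genotype and treatment, with points for libraries and bars for mean and SD of 4. With both agents Cxcl10 averaged 216 CPM in wild-type and 847 CPM in mutant libraries.

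The last comparisons asked whether the agents together changed a gene by more or less than the sum of their single log2 responses. In wild-type cells 88 genes departed from that sum in edgeR, 51 above and 37 below it, and in mutant cells 276 did, 206 above and 70 below. In wild-type cells MHC class I genes lay above it in 10 of 19 cases, while most members of the other interferon-induced lists did not depart from it past the threshold. Acod1 lay above the sum in both genotypes. In wild-type cells it had 0.660 CPM with vehicle, 0.440 with IFNg, 1.36 with Pam3CSK4 and 8.34 with both (departure 3.21 ± 0.21, edgeR adjusted p = 2.5e-12), and in mutant cells 0.388, 0.438, 7.17 and 55.3 CPM (2.77 ± 0.23, edgeR adjusted p = 8.1e-10).

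The wild-type count rested on single libraries. It was 44, 51, 51, 47, 53 and 45 without combination library 1, combination library 3, IFNg library 2, Pam3CSK4 library 1, Pam3CSK4 library 4 and vehicle library 1. It was 461, 1156 and 44 without vehicle library 2, 3 and 4. It was 154 with the libraries of this comparison alone, 501 in DESeq2, 172 with no filter, 43 with the structural share as a covariate and 20 without vehicle libraries 1 and 4. Cxcl10 lay above the sum in wild-type cells (1.76 ± 0.20, edgeR adjusted p = 6.2e-06). The GTPase gene Ifi47, Mpeg1 and the MHC gene H2-T23 also lay above it, by 1.01 ± 0.15, 0.43 ± 0.08 and 0.55 ± 0.07. Among lists, MHC class I genes had 10 of 19 members above the sum, or 18 adjusted over the list alone (median 0.27, camera adjusted p = 5.1e-20). GTPases had 4 of 18, or 6 adjusted over the list alone (median 0.53, camera adjusted p = 9.9e-17), and antiviral genes 3 of 32, or 13 adjusted over the list alone (median 0.32, camera adjusted p = 2.3e-11). Cytokines had 2 of 26 above, or 3 above and 1 below adjusted over the list alone (median 0.14, camera adjusted p = 0.008). Irf1, Irf8, Tlr1, Tlr2, Tlr6, Ifngr1, Ifngr2 and Cd14 did not depart past the threshold.

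In mutant cells the genes above the sum included Il15 (1.08 ± 0.10, edgeR adjusted p = 6.3e-09), Irf1 (0.57 ± 0.06), Tap1 (0.56 ± 0.06), Tlr2 (0.74 ± 0.14), Ifngr2 (0.42 ± 0.07), Rag1 (0.52 ± 0.06) and the antiviral kinase gene Cmpk2 (0.85 ± 0.11). Below the sum lay Icosl (-2.73 ± 0.21), Tubb3 (-2.07 ± 0.20), Slfn2 (-1.91 ± 0.21), Gbp3 (-1.03 ± 0.13) and the activation marker gene Cd69 (-0.76 ± 0.10). Cd40 was undetected with vehicle and had 0.519 CPM with IFNg, 4.20 with Pam3CSK4 and 36.9 with both. Interferon signalling genes had 4 of 22 above and 1 below (median 0.07, camera adjusted p = 6.3e-04), antiviral genes 5 of 32 above (median 0.17, camera adjusted p = 5.7e-04), and mast cell genes 2 of 15 above, or 4 adjusted over the list alone (median 0.25, camera adjusted p = 6.0e-05). Cytokines had 3 of 26 above and 2 below, or 5 and 6 adjusted over the list alone (median 0.19, camera adjusted p = 0.0024). Irf8, Tlr1, Tlr6, Ifngr1 and Cd14 did not depart past the threshold.

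**Figure D5:**
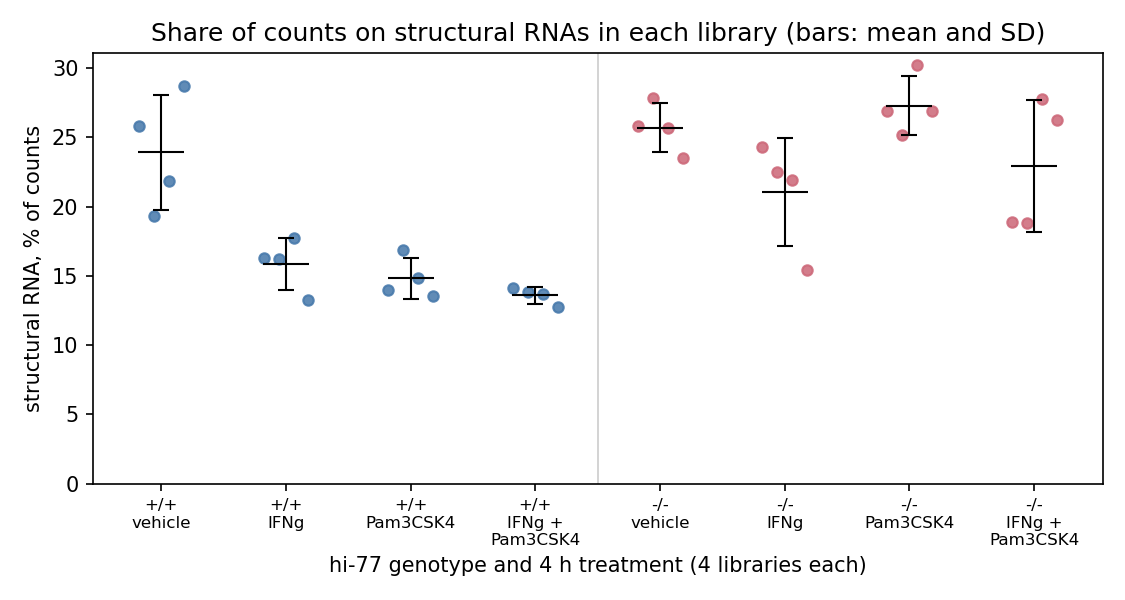
Share of counts in structural, micro- and mitochondrial RNA genes, in percent, for each of the 32 libraries by genotype and treatment, with points for libraries and bars for mean and SD of 4. The wild-type groups averaged 23.9% with vehicle and 13.6 to 15.9% after treatment, and the mutant groups 21.0 to 27.3%.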

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

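The count with the structural RNA share as a covariate, the comparison of treated levels, all tests for wild-type RNA in mutant libraries and the ratio of the Y-linked genes were tests chosen only after the result was seen.

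Gaps within groups of 4 libraries were tested for library totals, the share of the top 10 genes, list scores and the genes named in every comparison. A library lay far from the other 3 in 14 of 320 tests, where chance alone gives 16. The total of wild-type Pam3CSK4 library 1 was 60.42 M expected counts against 49.27 to 50.56 in the others, and that of mutant vehicle library 2 was 50.27 M against 61.92 to 64.31. Among genes, Tlr6 in mutant IFNg library 3 was 4.133 CPM against 3.323 to 3.446, Nfkbia in mutant combination library 3 was 54.79 against 49.41 to 50.01, and Cd14 in wild-type vehicle library 3 was 4.119 against 4.63 to 4.671. Scores far from the others were the GTPase list in mutant vehicle library 3 (-1.157 against -1.376 to -1.35), the NF-kB list in wild-type IFNg library 2 (1.94 against 2.049 to 2.065) and the complement list in wild-type IFNg library 4 (2.065 against 1.94 to 1.945). The megakaryocyte list was 0.6941 in mutant vehicle library 3 against 0.9153 to 0.918, and the glycolysis list 7.693 in mutant vehicle library 1 against 7.714 to 7.718. The neutrophil list was 3.885 in wild-type IFNg library 4 against 4.087 to 4.104, and 2.277 in mutant combination library 4 against 2.07 to 2.101. The monocyte list was 2.762 in wild-type combination library 2 against 2.686 to 2.693, and 3.138 in mutant combination library 4 against 3.046 to 3.054.

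The treatment responses differed between genotypes, by the edgeR test of the difference itself, for 245 genes with IFNg, 3956 with Pam3CSK4 and 2347 with both agents. With IFNg the lists called by camera had median differences of -0.182 (GTPases), -0.056 (interferon signalling), 0.229 (cytokines), 0.008 (NF-kB targets) and 0.381 (immediate-early genes). With an estimated correlation only the cytokine call held, the adjusted p of the others being 0.137, 0.0837, 0.206 and 0.226. The GTPase call also ended with a prior count of 0.5 (0.669) and that for interferon signalling with the structural share as a covariate (0.0728). The NF-kB call (adjusted p = 0.0345) ended without mutant IFNg library 4 (0.107), wild-type IFNg library 2 (0.0844) or wild-type vehicle library 3 (0.0631). With Pam3CSK4 they were 0.111 (MHC class I), 0.689 (cytokines), 0.905 (NF-kB targets), 0.212 (complement), -0.088 (cell cycle) and 0.151 (cholesterol synthesis). Cytokines and NF-kB targets held with an estimated correlation, while MHC class I (0.374), complement (0.194), cell cycle (0.197) and cholesterol synthesis (0.285) lost the call. With the structural share as a covariate MHC class I (0.0549) and cell cycle (0.126) lost it too. The cell cycle call (adjusted p = 0.0276) ended without wild-type vehicle library 3 (0.0514). With both agents they were 1.05 (cytokines), 0.918 (NF-kB targets), 0.429 (immediate-early genes), 0.244 (complement), 0.229 (erythroid), -0.081 (cell cycle) and 0.313 (cholesterol synthesis). With an estimated correlation immediate-early (0.395), complement (0.101), cell cycle (0.205) and cholesterol synthesis genes (0.0607) lost the call. The erythroid call ended with a prior count of 0.5 (0.0763) and with the structural share as a covariate (0.0647), as did that for cell cycle with the share (0.0947). The immediate-early call (adjusted p = 0.00997) ended without wild-type vehicle library 3 (0.075), and the cell cycle call (0.0318) ended without mutant vehicle library 2 (0.0513), wild-type combination library 4 (0.0564) or wild-type vehicle library 3 (0.0599).

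Among the genes reported in every comparison, the IFNg response in mutant minus wild-type cells differed for Ifngr1 (-0.254, edgeR adjusted p = 0.0161), Tlr6 (-0.722, 0.0116), Irf1 (-0.511, 4.3e-07) and Irf8 (-0.618, 2.65e-07). The Pam3CSK4 response differed for Ifngr1 (-0.394, 7.43e-06), Ifngr2 (0.34, 0.000291), Irf1 (-0.466, 1.5e-06), Nfkbia (0.919, 1.71e-09) and Tnfaip3 (2.205, 2.26e-15). The response to both agents differed for Ifngr1 (-0.546, 1.83e-08), Ifngr2 (0.569, 9.65e-08), Tlr6 (-0.525, 0.0226), Irf1 (-0.522, 4.41e-08), Irf8 (-0.619, 3.69e-08), Nfkbia (0.983, 3.26e-10) and Tnfaip3 (2.484, 4.03e-17).

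Splits of the same libraries into other groups, fitted on those libraries alone, were set beside the real one. In the 7 comparisons of a pair of groups the real split called 6562, 3855, 2057, 5284, 4775, 3923 and 6127 genes, in the order mutant against wild-type, wild-type IFNg, Pam3CSK4 and both, mutant IFNg, Pam3CSK4 and both. It was the only one of 35 splits to call so many, the highest of the others calling 0, 2, 0, 0, 0, 2 and 0. A chance division of the libraries is thus an unlikely source of these counts. The other splits mix the 2 groups, so any steady difference between groups, of whatever origin, would give this result. They do not separate genotype or treatment from library composition. For the other 5 results the splits hold no value for no change. Those of a difference exchanged the genotypes within a treatment and those of non-additivity exchanged all 16 libraries, which turns the large effects of genotype or agent into spread, or into the contrast itself. The median of the other splits was 0 genes in each, and the larger ones follow the structure of the samples: those of the Pam3CSK4 difference put the genotypes on opposite sides in vehicle and treated libraries. The number of the 100 splits with as many genes, the real one among them, was 1 for the IFNg difference (127 real, 12 highest other), 6 for the Pam3CSK4 difference (3718 and 8376) and 2 for that with both agents (1894 and 2372). It was 5 for wild-type non-additivity (154 and 3409) and 3 for mutant non-additivity (217 and 1578). Nothing about chance is read from these.

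Pam3CSK4 changed many genes by small amounts in wild-type cells, in libraries that also had a lower structural RNA share than vehicle. A difference in library composition along that share is a candidate explanation: with the share as a covariate 155 genes were called in place of 3277, as this explanation needs. That model gives each gene 1 slope on the share for all 32 libraries. Slopes fitted within the wild-type and within the mutant groups had a correlation of only 0.374 across genes, which limits what the count shows. Slopes on the share fitted in the mutant libraries alone had a correlation of -0.305 across 14825 genes with the wild-type changes (rank correlation -0.505; genes are not independent replicates), between the bounds of -0.5 and -0.2 set beforehand. Over the 3247 called genes alone the correlation was -0.555, which goes with this explanation, though these genes were chosen for their change. It stays open. It is argued against as the whole cause for NF-kB targets, of which 21 of 27 called members stayed called with the covariate (median 1.02 ± 0.07 before and 1.07 ± 0.088 after). An effect of Pam3CSK4 itself on the other genes, and on the share, stays open, because share and treatment go together in wild-type cells.

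NF-kB targets rose more with Pam3CSK4 in mutant than in wild-type cells. The structural RNA share is argued against as the cause, since 21 of 23 members stayed called with it in the model (median 1.11 ± 0.098 before and 1.06 ± 0.111 after). Lower starting levels in mutant cells are argued against as the whole cause, since 21 of 23 members were also higher in level in mutant than in wild-type Pam3CSK4 libraries (median 0.795; 1 lower), while with vehicle 6 were higher and 11 lower (median -0.217). A stronger response of mutant cells may explain the pattern, possibly through the higher Tlr1 and Tlr2 of these cells, which was not tested. Other differences between the lines, of which there was 1 per genotype, stay open.

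Mutant libraries held both Xist, the RNA of the inactive X chromosome, and RNA from Y-linked genes. Xist averaged 485 ± 63 CPM (SD, n = 16 mutant libraries), with 17404 to 37062 counts per library, against 0 to 5 counts in wild-type libraries, and with vehicle Ddx3y, Eif2s3y, Uty and Kdm5d stood at 21.6, 21.9, 22.4 and 22.8% of their wild-type CPM. A mutant line that mixes XX and XY cells is a candidate explanation. With vehicle the highest of the Y-linked ratios was 1.059 times the lowest, as any single source of XY cells would give. The ratios were tested with vehicle only and lay further apart with Pam3CSK4 and with both agents. With Pam3CSK4 Uty had 15.4 to 20.6 CPM in mutant and 46.8 to 54.8 in wild-type libraries, and Kdm5d 8.79 to 11.2 and 43.2 to 44.8. With both agents Uty had 13.9 to 19.8 CPM in mutant and 46.6 to 54.3 in wild-type libraries, and Kdm5d 8.09 to 10.1 and 41.6 to 45.6. X-linked genes known to escape inactivation had a median log2 fold change of 0.486 (quartiles 0.047 and 1.10), with 7 of 10 tested higher and Ddx3x lower (-0.10). Kdm6a rose by 0.64. Ftx (4.54), Mid1 (1.53) and Jpx (1.25) rose more than an extra active copy gives, and Utp14a (0.01) and Pbdc1 (-0.04) did not pass. Wild-type RNA or cells as the source of all Y-linked RNA in the mutant libraries are argued against: they would leave every wild-type transcript at 21.6% of its level or more, yet 15 genes of at least 20 CPM had every mutant vehicle library under 0.5 of what that share would leave, among them Ms4a2 (1.76% of its wild-type level) and Il1rl1 (2.79%). Pir and Pklr had no counts in mutant vehicle libraries. Before this test was chosen, stricter bounds had been missed: the 50 most reduced genes of at least 20 CPM kept a median ratio of 0.164 where a value under 0.0222 was asked for, and 15 of 9153 genes lay under 2.16% of their wild-type level where 20 were asked for. A smaller wild-type share beside another source of Y-linked RNA stays open only within what the most reduced transcripts leave. Dst stood at 0.361% and Prg2 at 0.607% of wild-type level with vehicle, and Pir was at least 612-fold lower. Such a share could supply little of the Y-linked RNA, which stood at 21.6 to 22.8%.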

How the results depend on the processing

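The structural RNA share as a covariate and the fits without wild-type vehicle libraries 1 and 4 or mutant combination libraries 3 and 4, the highest in that share within their group, were chosen only after the data were seen; the other settings were planned. Where a value moved, the cause was not tested unless the setting itself shows it.

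Requiring a 2-fold change left 2098, 472, 189, 691, 460, 275, 818, 24, 271, 212, 11 and 19 genes, in the order mutant against wild-type, wild-type IFNg, Pam3CSK4 and both, mutant IFNg, Pam3CSK4 and both, the differences for IFNg, Pam3CSK4 and both, and wild-type and mutant non-additivity, by its own construction. With the share as a covariate the wild-type counts were 2739 (IFNg), 155 (Pam3CSK4) and 3361 (both), the differences 1080 (Pam3CSK4) and 1216 (both), and wild-type non-additivity 43. Without wild-type vehicle libraries 1 and 4, a fit with fewer samples, wild-type Pam3CSK4 called 648, its difference between genotypes 2444 and wild-type non-additivity 20. Without mutant combination libraries 3 and 4 the difference for both agents was 1274. Fits of each comparison's libraries alone gave 2057 for wild-type Pam3CSK4, 127 for the IFNg difference and 154 for wild-type non-additivity; DESeq2 gave 400 and 501 for the latter pair, and no filter gave 172 for wild-type non-additivity. All other counts under these settings, and all counts under RLE size factors, a CPM filter and structural RNAs left out, lay within 1.5 times those reported. The share of rises moved from 47 to 91% for wild-type Pam3CSK4 with the covariate, from 58 to 85% for wild-type non-additivity without vehicle libraries 1 and 4, from 50.2 to 37.4% for the IFNg difference with the CPM filter and from 55.7 to 37.5% for that of both agents with its libraries alone. At 2-fold it moved from 53.8 to 83% for the Pam3CSK4 difference, from 47.2 to 77.5% for mutant Pam3CSK4 and from 74.6 to 47.4% for mutant non-additivity.

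Leaving out each library in turn gave 7433 to 8076, 4305 to 5339, 2048 to 4099, 5777 to 6456, 4333 to 4672, 2966 to 3537, 6096 to 6335, 136 to 382, 3357 to 4583, 1753 to 2956, 44 to 1156 and 207 to 339 genes in the same order. Wild-type Pam3CSK4 fell to 2048 without vehicle library 4. The IFNg difference was 136 without mutant IFNg library 1, 159 and 157 without wild-type IFNg library 2 or 3, and 382 and 138 without wild-type vehicle library 2 or 4. Wild-type non-additivity was 44 and 51 without combination library 1 or 3, 51 without IFNg library 2, 47 and 53 without Pam3CSK4 library 1 or 4, and 45, 461, 1156 and 44 without vehicle library 1, 2, 3 or 4.

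Library numbers did not pair the groups: residual correlations averaged -0.005 for the same number and 0.001 for others, and 7 of 32 libraries were closest to their own number. A block for the number gave 7917, 5190, 3202, 6407, 4903, 3575, 6469, 258, 3917, 2303, 88 and 288 genes.

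Of the 109 list calls, 66 held with an estimated correlation. There were 105 calls with a prior count of 0.5, 108 with RLE size factors, 112 with the block and 110 with the share, which kept 97 of the 109. Of 513 results for genes named in the text, 512 kept their side of the threshold with RLE size factors, 495 with no filter, 510 with the CPM filter, 509 with the block, 512 with structural RNAs left out and 469 with the share. DESeq2 kept 507 of 512, the libraries of each comparison alone 488 of 509, the fits without a pair of libraries 301 of 338 (wild-type vehicle) and 124 of 133 (mutant combination), and leave-one-out fits 5312 of 5536; the others weakened or strengthened, apart from 2 that reversed. These were Uty and Eif2s3y, which with the share as a covariate turned from a fall to 0.033 and 0.019 with both agents in wild-type cells. At these totals 76.1% of genes set to differ 1.5-fold in their response were recovered in simulated data for Pam3CSK4, which limits what small differences show.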

Other observations

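No test in this part was chosen after a result was seen. Mean fragment lengths lay between 224.7 and 241.5 bases. The structural RNA share of single libraries ran from 12.7 to 30.2%. The genes that fell with Pam3CSK4 in both genotypes numbered 165, where independent lists would share 222.9, against 1272 with IFNg, where independent lists would share 390.6, and 1635 with both agents, where they would share 671.9.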
